A study of Mus musculus with 15 samples.

How the data were processed

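Kidney RNA was profiled in 15 libraries from wild-type C57BL/6 mice, in 3 groups of 5: control, cisplatin and lipopolysaccharide (LPS), all collected 48 h after a single injection. Per the labels' protocols, total RNA was depleted of ribosomal RNA with biotinylated probes before random-primed library construction, and the doses are not given. The labels name the control injection as saline in the protocol and as HBSS in the sample characteristics, and do not say that each library came from a separate animal. The submitters' processing notes name bcl2fastq 2.0, HISAT2, StringTie, DESeq2, limma and the mm10 genome, without saying what each was used for.

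The main table holds estimated counts per gene as deposited by the authors, not scaled for depth or gene length, for 56980 Ensembl genes. Between 9.63% and 12.8% of its values per library were not whole numbers. The deposited signal in the other table, which its name calls FPKM, was tested against these counts. Each of its values was a whole read count divided by 1 factor per library, to within 0.01 of a read, and between 99.8% and 99.9% of the 30368 uniquely matched genes per library gave the rounded count of the main table. That table of 30453 genes was therefore treated as depth-scaled counts, not as FPKM, and served only for alternative settings. The design fixed beforehand allowed for either counts or FPKM, and the rule for counts was used.

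Estimated counts were rounded and analysed with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr, 1 model over the 3 groups without an intercept, and the quasi-likelihood test. The filter left 16666 genes. P-values were adjusted by the Benjamini-Hochberg method over those genes in each comparison, two-sided, with a threshold of 0.05 and no minimum fold. Comparisons were cisplatin against control, LPS against control and cisplatin against LPS. Values are given as CPM after TMM scaling, as mean ± SD over 5 libraries, and fold changes are ratios of those means. A group without counts was given a floor of 3 counts over its 5 libraries, and a group with 1 to 3 counts a 95% counting interval. These limits cover counting error only. Each SE is the absolute log2 fold change divided by the square root of the F statistic of the quasi-likelihood test. For genes near 0 counts in a group it can understate the uncertainty. The series title's genes, Slc34a1 and Slc34a3, and 3 injury markers were also tested with two-sided exact permutation tests of 5 against 5 log2 values, 15 tests in all.

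Of 41 gene lists written before the data were examined, 39 had at least 5 tested members. Each was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset correlation between genes of 0.01 and adjustment over the 39 lists. The lists hold 977 genes, 41 of them in more than 1 list. Camera was also run with the correlation estimated per list, and that adjusted p is given beside each call. A list of platelet genes was written later, before its values were seen. Cell type lists were read as gene lists in whole tissue, not as counts of cells.

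The text names genes by a rule fixed before the data were examined. It takes the title's genes and Havcr1, Lcn2 and Cdkn1a, then the 8 largest rises and 8 largest falls against control, or 5 each between treatments. Those genes had passed the threshold, with groups that did not overlap and a mean of at least 5 CPM in the higher group. To these it adds up to 4 members per list described, and up to 2 members that did not pass. For some lists fewer members are named, passing over genes near 0 counts, and each gene is reported in the comparisons where it is named. Both restrictions, and the naming of Slc25a37, Nfil3 and Cry1, were made after values were seen. Results of 2 genes are not reported here, and those genes were left out of the tests of single libraries. Members of near-identical families (Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, Saa, Serpina3, Gbp, Sprr2, Hsd3b and Nat8f genes) may share reads, so their individual values are uncertain. How strand was used in counting is not stated. Gene coordinates and spans came from GENCODE M21 (GRCm38, the assembly also called mm10), which matched 52125 of the gene IDs. Of the IDs, 1542 had no symbol, 253 of them among the genes tested.

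The steps were tested on simulated counts for 16666 genes with known changes. For cisplatin against control, edgeR recovered 67.2%, 86.6% and 98.5% of genes changed 1.5-, 2- and 4-fold, and 3.61% of its calls were false. For LPS against control it recovered 50.7%, 82.1% and 97%, with 4.97% false calls. For cisplatin against LPS it recovered 65.7%, 85.1% and 100%, with 6.53% false calls. DESeq2 1.42.0 made 11.7%, 18.7% and 17.8% false calls in the same 3 simulations. Each simulation changed 67, 67 and 66 genes 1.5-, 2- and 4-fold and raised a list of 20 others, with edgeR's own estimate of spread per gene. That is a far smaller share of genes than the real comparisons called. The share of false calls depends on how many genes change, so these rates need not hold for the real data. Alternatives to the scaling, filter, test, samples in the fit and threshold were run, each library was left out in turn, and the replicate number was added as a block. Settings added after the data were examined were total-count scaling, the whole reads recovered from the depth-scaled table, and cisplatin libraries 3 to 5 alone.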

Results

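Kidney transcriptomes were compared 48 h after a single intraperitoneal injection in 3 groups of 5 mouse kidney libraries. The groups were control, cisplatin, a platinum chemotherapy drug known to injure the proximal tubule, and lipopolysaccharide (LPS), the bacterial endotoxin used to model septic kidney injury. The 15 libraries held 20983327 to 28147229 estimated counts, and 16666 of 56980 genes were tested. Pearson r of log2 CPM across genes was 0.969 to 0.990 between libraries of the same group and 0.849 to 0.931 between groups. Principal components 1 and 2 carried 53.5% and 29.6% of the variance. Genes with at least 10 counts numbered 16560 ± 165 per cisplatin library (SD, n = 5), against 15389 ± 149 in control and 15441 ± 135 in LPS. The share of counts from the mitochondrial genome was 6.52% ± 0.534 in control, 4.88% ± 0.412 after cisplatin and 4.24% ± 0.441 after LPS.

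The series title names lower Slc34a1 and Slc34a3 as possible marks of kidney injury by toxins. Slc34a1 (ENSMUSG00000021490; chromosome 13, 55398187 to 55415592, GRCm38) and Slc34a3 (ENSMUSG00000006469; chromosome 2, 25228898 to 25234364) encode the sodium-phosphate cotransporters of the proximal tubule brush border. Slc34a1 stood at 8481 ± 1175 CPM in control, 85.0 ± 18.8 CPM after cisplatin and 1922 ± 283 CPM after LPS (SD, n = 5). It was 99.8-fold lower after cisplatin (log2 fold change -6.64, SE 0.19, edgeR adjusted p = 9.49e-14) and 4.41-fold lower after LPS (-2.14, SE 0.155, adjusted p = 3.52e-09). Slc34a3 stood at 83.5 ± 11.9, 0.604 ± 0.375 and 14.2 ± 1.88 CPM in the same order. It was 138-fold lower after cisplatin (-7.06, SE 0.258, adjusted p = 9.89e-13) and 5.86-fold lower after LPS (-2.55, SE 0.19, adjusted p = 5.04e-09). Cisplatin lowered both further than LPS did, with log2 differences of -4.50 (SE 0.172, adjusted p = 3.68e-12) and -4.51 (SE 0.255, adjusted p = 3.46e-10). No control, cisplatin or LPS value of either gene overlapped another group's, and each exact permutation test gave p = 0.0079, the smallest that its 252 arrangements allow (adjusted p = 0.0079 over 15 tests). The series title names both genes, so these tests are not independent evidence for them.

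**Figure D1:**
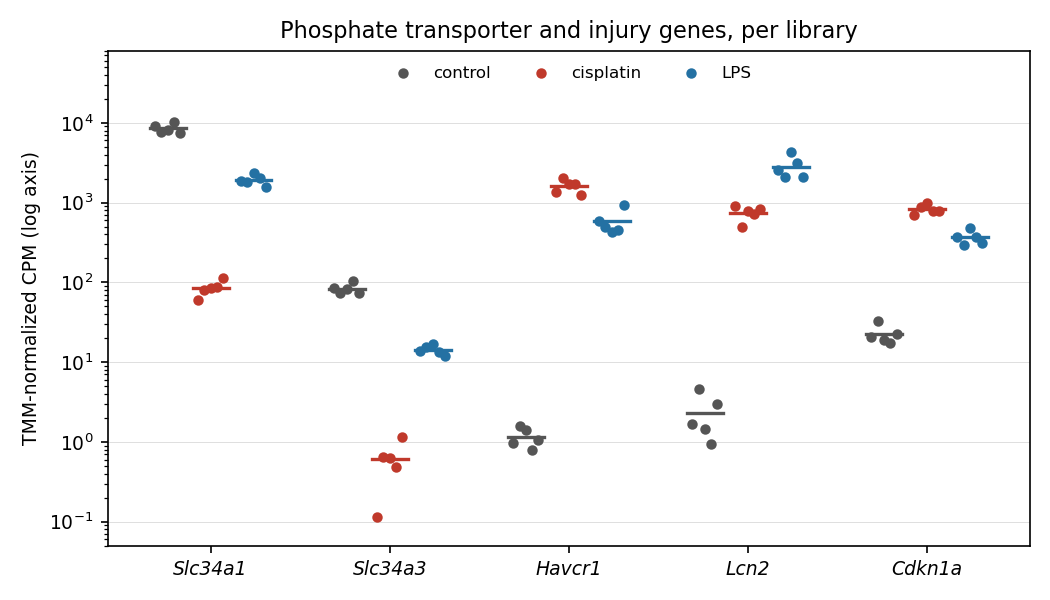
Level of each named gene per library in CPM on a log axis, for control, cisplatin and LPS (5 libraries each, points), with a line at the group mean. Slc34a1 averaged 8481 CPM in control, 85.0 after cisplatin and 1922 after LPS, and Slc34a3 averaged 83.5, 0.604 and 14.2.

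Other phosphate genes moved in both directions. Kl, which encodes Klotho, the co-receptor for the phosphate-lowering hormone FGF23, fell 14.5-fold after cisplatin (-3.86, SE 0.15, adjusted p = 1.73e-12) and 7.61-fold after LPS (-2.93, SE 0.144, adjusted p = 3.11e-11). Slc34a2, the sodium-phosphate cotransporter best known from lung and gut, rose from 5.90 ± 1.52 CPM in control to 83.9 ± 15.3 after cisplatin (3.83, adjusted p = 4.46e-11) and 155 ± 33.9 after LPS (4.71, adjusted p = 7.23e-12). After LPS, Slc20a1, a widely expressed phosphate transporter, rose (2.86, adjusted p = 1.37e-11), and Pdzk1, a scaffold of brush-border transporters, fell (-2.66, adjusted p = 1.76e-10). Of 18 phosphate-handling genes tested, 6 rose and 11 fell after cisplatin (17 adjusted over the list alone), with a median of -0.84. The list passed camera (adjusted p = 0.014, adjusted p = 0.42 with an estimated correlation). After LPS, 5 rose and 11 fell (16 adjusted over the list alone), with a median of -0.87, and the list did not pass (adjusted p = 0.091). Because the list holds the title's genes, its direction is not independent evidence. Fgfr1, an FGF receptor of the list, did not pass after cisplatin (-0.10, adjusted p = 0.186), and under total-count scaling its value was 0.28 (adjusted p = 0.00331).

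After cisplatin, kidneys showed strong induction of tubular injury genes together with loss of transcripts of the differentiated tubule. Havcr1, which encodes the injury marker KIM-1, rose from 1.16 ± 0.317 CPM to 1613 ± 311 (SD, n = 5; log2 fold change 10.44, SE 0.306, adjusted p = 1.15e-13). Lcn2, which encodes the injury marker NGAL, rose from 2.31 ± 1.46 to 741 ± 156 CPM (8.31, SE 0.386, adjusted p = 1.36e-11). Cdkn1a, the p53 target that halts the cell cycle, rose from 22.5 ± 6.02 to 822 ± 110 CPM (5.19, SE 0.193, adjusted p = 1.18e-12). Egf, a growth factor made by the thick ascending limb and distal tubule, fell from 3066 ± 420 to 32.1 ± 13.1 CPM (-6.57, SE 0.301, adjusted p = 1.15e-11). In all, 11947 of 16666 genes (71.7%) changed, 6583 higher and 5364 lower, of which 5604 changed at least 2-fold (3328 higher, 2276 lower). The balance of directions depended on scaling. With total-count scaling 9464 were higher and 3425 lower, or 73.4% higher against 55.1%, and the median log2 fold change of all tested genes was 0.49 against 0.11.

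Among the largest rises, Sprr2f, a cornified-envelope protein gene, was at least 1567-fold higher than in control libraries, where it had 0 counts (adjusted p = 5.92e-11). Krt20, a keratin of injured epithelium, rose 2938-fold (11.48, SE 0.263, adjusted p = 1.07e-14), and Fosl1, a subunit of the AP-1 transcription factor, rose 2162-fold (10.83, SE 0.407, adjusted p = 1.25e-12). Crct1, from the epidermal differentiation gene cluster, was at least 517-fold higher (adjusted p = 3.6e-08), Vgf, a neuropeptide precursor gene, at least 414-fold higher (adjusted p = 1.27e-08), and Serpina3m, a serine protease inhibitor gene, at least 248-fold higher (adjusted p = 5.06e-08). Slpi, an antiprotease gene with 1 count in control, rose 2406-fold (95% counting interval 432 to 95080, adjusted p = 1.72e-13), and its log2 fold change was 12.04 without control replicate 2, against 10.59 with all libraries. Of 30 tubular injury genes tested, 30 rose (30 adjusted over the list alone), with a median of 3.92. The list passed camera (adjusted p = 1.2e-14, adjusted p = 0.11 with an estimated correlation).

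Of 39 proximal transporter genes, 37 fell and 2 rose (39 adjusted over the list alone, camera adjusted p = 6.4e-14, adjusted p = 0.23 with an estimated correlation). Slc7a13, an amino acid transporter gene, fell 82.2-fold (-6.36, SE 0.27, adjusted p = 4.75e-12), and Slc22a8, which encodes the organic anion transporter OAT3, fell 76.5-fold (-6.25, SE 0.149, adjusted p = 1.38e-14). All 38 proximal metabolism genes tested fell (38 adjusted over the list alone, camera adjusted p = 4.2e-17, adjusted p = 0.2 with an estimated correlation), with a median of -3.51. They included Miox, the inositol-degrading enzyme gene of the renal cortex (2231 ± 336 to 25.9 ± 2.39 CPM; -6.43, SE 0.129), and Gatm, a creatine synthesis gene (1285 ± 108 to 27.9 ± 5.05 CPM; -5.53, SE 0.148). Outside the lists, Slc22a28, of the organic anion transporter family, fell 161-fold (adjusted p = 1.07e-14), Nat8f6, of an acetyltransferase family, 151-fold (adjusted p = 4.56e-12), and Pde6a, a phosphodiesterase subunit gene, 143-fold (adjusted p = 4.69e-11).

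Thick limb, distal tubule and intercalated cell genes fell as well. Of 12 thick ascending limb genes, 11 fell (11 adjusted over the list alone), with a median of -2.11 (camera adjusted p = 0.00067, adjusted p = 0.42 with an estimated correlation). Cisplatin replicate 2 stood lowest of its group for this list, at 61.5 CPM for Umod, the uromodulin gene, against 771 to 1810 CPM in the other 4 cisplatin libraries. Of 13 distal tubule genes, 12 fell (12 adjusted over the list alone, camera adjusted p = 2.5e-06, adjusted p = 0.12 with an estimated correlation). Slc12a3, the thiazide-sensitive sodium chloride cotransporter gene, fell 14.5-fold (-3.86, SE 0.154, adjusted p = 2.35e-12), and Pvalb, a calcium-binding protein gene, fell 119-fold (-6.82, SE 0.277, adjusted p = 2.92e-12). Among 12 intercalated cell genes, 8 fell and 2 rose (10 adjusted over the list alone, camera adjusted p = 0.017, adjusted p = 0.37 with an estimated correlation). Slc4a1, the anion exchanger gene of acid-secreting cells and red cells, was among those that fell (-3.84, SE 0.352, adjusted p = 4.52e-08). Of 12 collecting duct genes, 6 fell (6 adjusted over the list alone) and the list did not pass (adjusted p = 0.16). Its member Hsd11b2, which protects the mineralocorticoid receptor from cortisol-like steroids, fell (-1.58, SE 0.252, adjusted p = 2.68e-05).

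All but 3 of 57 oxidative phosphorylation genes fell (54 adjusted over the list alone, camera adjusted p = 2e-15, adjusted p = 0.32 with an estimated correlation), among them Ndufs1, a complex I subunit gene (-1.87, SE 0.0937, adjusted p = 3.28e-11). Of 13 mitochondrial genome transcripts, 12 fell (12 adjusted over the list alone, camera adjusted p = 0.00019, adjusted p = 0.3 with an estimated correlation), including mt-Nd3 (-2.11, SE 0.188, adjusted p = 3.19e-08). For fatty acid oxidation, 24 of 36 genes fell and 6 rose (30 adjusted over the list alone, camera adjusted p = 0.00019, adjusted p = 0.51 with an estimated correlation). Against the list's direction, Pdk4, the kinase that turns off pyruvate oxidation, rose 6.88-fold (2.78, SE 0.155, adjusted p = 1.08e-10). Cholesterol synthesis genes fell in 20 of 24 cases (21 adjusted over the list alone, camera adjusted p = 1.3e-07, adjusted p = 0.12 with an estimated correlation), led by Cyp51, the lanosterol demethylase gene (-3.52, SE 0.105, adjusted p = 1.33e-13). Of 11 renin-angiotensin genes, 7 fell and 1 rose (8 adjusted over the list alone, camera adjusted p = 0.017, adjusted p = 0.23 with an estimated correlation).

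The p53 program, cell cycle genes and cell death genes rose. Of 35 p53 target genes, 32 rose and 2 fell (34 adjusted over the list alone, camera adjusted p = 1.8e-11, adjusted p = 0.11 with an estimated correlation). Psrc1, a spindle protein gene, rose 116-fold (6.87, SE 0.186, adjusted p = 6.24e-14), and Eda2r, a TNF receptor family gene, rose 103-fold (6.69, SE 0.215, adjusted p = 2.51e-13). Of 48 cell cycle genes, 44 rose (44 adjusted over the list alone, camera adjusted p = 1.1e-05, adjusted p = 0.51 with an estimated correlation), including Ccne2, cyclin E2 (2.55, SE 0.324, adjusted p = 2.2e-06), and Bub1, a mitotic checkpoint kinase gene (2.41, SE 0.484, adjusted p = 0.000278). The groups overlapped in the mean log2 CPM of this list, with cisplatin replicate 5 at 2.448 and control replicate 3 at 2.493. Of 36 cell death genes, 26 rose and 5 fell (31 adjusted over the list alone, camera adjusted p = 0.00011, adjusted p = 0.12 with an estimated correlation). Among them, the necroptosis genes Ripk3 (4.0, adjusted p = 2.18e-09) and Mlkl (3.97, adjusted p = 6.59e-11) and the inflammatory caspase gene Casp4 (4.34, adjusted p = 1.7e-08) rose. Ribosomal protein genes rose in 48 of 50 cases (48 adjusted over the list alone, camera adjusted p = 1.4e-10, adjusted p = 0.37 with an estimated correlation), with a median of 0.73 and Rps24 at 1.52 (SE 0.084).

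Inflammatory and matrix genes rose. Of 48 acute-phase and cytokine genes, 47 rose (47 adjusted over the list alone, camera adjusted p = 1.4e-14, adjusted p = 0.11 with an estimated correlation). The chemokine gene Ccl20 was at least 197-fold higher than in control, Il1rn, the interleukin-1 receptor antagonist gene, rose 318-fold (8.27, SE 0.334, or 8.88 without control replicate 1), and the neutrophil chemokine gene Cxcl1 rose 211-fold (7.71, SE 0.434). The exception was Nos2, inducible nitric oxide synthase (-1.34, SE 1.07, adjusted p = 0.269). In a fit of the groups compared alone Nos2 passed as lower (-1.39, adjusted p = 0.00108, the lowest of 25 settings, the highest being 0.434), and every cisplatin library (0.303 to 1.05 CPM) lay below every control (1.24 to 2.26 CPM). Of 44 interferon response genes, 43 rose (43 adjusted over the list alone, camera adjusted p = 5.7e-11, adjusted p = 0.3 with an estimated correlation), with Cxcl10 at 4.31 (SE 0.497). Among 27 complement genes, 18 rose and 4 fell (22 adjusted over the list alone, camera adjusted p = 0.0025, adjusted p = 0.11 with an estimated correlation), led by C3, the central component (5.23, SE 0.179). All 39 matrix and fibrosis genes rose (39 adjusted over the list alone, camera adjusted p = 8.7e-10, adjusted p = 0.3 with an estimated correlation), led by the protease inhibitor gene Timp1 (8.11, SE 0.337). Of 17 glucocorticoid response genes, 13 rose and 1 fell (14 adjusted over the list alone, camera adjusted p = 0.0025, adjusted p = 0.38 with an estimated correlation). Mt2, a metal-binding metallothionein gene, rose 43.0-fold (5.42, SE 0.273).

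Macrophage genes rose in 18 of 22 cases and fell in 2 (20 adjusted over the list alone, camera adjusted p = 0.00016, adjusted p = 0.26 with an estimated correlation). Chil3, a chitinase-like protein gene, rose 436-fold (8.73, SE 0.352, adjusted p = 2.69e-12), and Itgam, which encodes CD11b, rose 27.3-fold (4.76, SE 0.183, adjusted p = 1.53e-12). Neutrophil genes rose in 11 of 14 cases (11 adjusted over the list alone, camera adjusted p = 6.2e-05, adjusted p = 0.11 with an estimated correlation), with S100a9, a calprotectin subunit gene, at 7.17 (SE 0.386), or 7.92 without control replicate 4. Of 11 adipocyte genes, 4 rose (3 adjusted over the list alone) and the list did not pass (adjusted p = 0.67). Cidec, a lipid droplet gene, rose (4.96, SE 0.896, adjusted p = 1e-04), but cisplatin replicate 1 held 135 CPM against 12.2 to 18.9 CPM in the other 4, and without it the value was 3.63, while without control replicate 4 it was 6.00. Adipoq, the adiponectin gene, did not pass (3.21, SE 1.49, adjusted p = 0.0628), and without cisplatin replicate 1 its value was -0.52. Without control replicate 4 or cisplatin replicate 2, 4 or 5 it passed (adjusted p = 0.0347 to 0.0438).

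Globin and Alas2 transcripts were nearly lost after cisplatin. Of 9 erythroid genes, 7 fell and 1 rose (8 adjusted over the list alone), with a median of -7.78 (camera adjusted p = 0.0012, adjusted p = 0.2 with an estimated correlation). The adult beta-globin gene Hbb-bs fell from 308 ± 90.8 to 0.299 ± 0.109 CPM (-9.98, SE 0.396, adjusted p = 2.17e-12), and Hbb-bt was at least 2169-fold lower, with 0 counts after cisplatin (adjusted p = 1.09e-08). The alpha-globin genes Hba-a2 (-9.34, SE 0.406, adjusted p = 6e-12) and Hba-a1 (-8.78, SE 0.468, adjusted p = 6.68e-11) fell alike, and Hba-a1 was at -9.60 without cisplatin replicate 1. Alas2, the first enzyme of heme synthesis in developing red cells, fell from 8.96 ± 3.27 to 0.0357 ± 0.00287 CPM (-7.78, SE 0.51, adjusted p = 7.45e-10). It had 5 counts over the 5 cisplatin libraries, 1 in each, so the SD there reflects depth and not spread between samples. Epb42, a red cell membrane protein gene, did not pass (-0.23, SE 0.428, adjusted p = 0.637), and its value was 0.14 under total-count scaling. Slc25a37, a mitochondrial iron importer gene, was the member that rose (0.71, SE 0.0694, adjusted p = 9.91e-08), and the list kept 0.0117% of counts against 0.0861% in control.

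After LPS, Saa3, an acute-phase serum amyloid gene, rose from 1 count in the 5 control libraries to 169 ± 26.6 CPM (SD, n = 5; log2 fold change 13.55, SE 0.264, adjusted p = 3.38e-15), a ratio of 19100 (95% counting interval 3428 to 754600), and without control replicate 4, which held that count, the log2 fold change was 15.01. Gbp2, an interferon-induced GTPase gene, rose from 10.4 ± 0.987 to 5360 ± 842 CPM (9.01, SE 0.207, adjusted p = 7.55e-15). The fibrinogen genes Fgb (10.07, SE 0.277, adjusted p = 4.83e-14) and Fgg (9.49, SE 0.266, adjusted p = 4.95e-14) rose to 3189 ± 418 and 7877 ± 430 CPM. Lcn2 rose to 2828 ± 910 CPM (10.25, SE 0.413, adjusted p = 3.19e-12), Havcr1 to 581 ± 207 CPM (8.96, SE 0.293, adjusted p = 2.39e-13) and Cdkn1a to 366 ± 74.9 CPM (4.02, SE 0.183, adjusted p = 1.26e-11). In all, 11057 genes (66.3%) changed, 5751 higher and 5306 lower, of which 4545 changed at least 2-fold (2383 higher, 2162 lower).

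All 48 acute-phase and cytokine genes rose after LPS (48 adjusted over the list alone, camera adjusted p = 2.7e-21, adjusted p = 0.061 with an estimated correlation), with a median of 4.61. The acute-phase gene Orm2 was at least 2017-fold higher than in control and Acod1, the itaconate synthesis gene of activated macrophages, at least 1036-fold higher. Orm2 held 132 CPM in LPS replicate 5 against 10.6 to 63.0 in the other LPS libraries, and its log2 fold change went from 13.36 to 12.7 without it. Acod1 held 71.8 CPM in LPS replicate 3 against 10.9 to 28.4 in the others, and went from 12.39 to 11.67 without it. Saa2 rose from 3 control counts to 257 ± 102 CPM, a ratio of 9873 (95% counting interval 3378 to 47880), and Saa1 rose 4171-fold (11.93, SE 0.568). Without control replicate 2, which held those counts of Saa2 and the most Saa1, the log2 fold changes were 15.61 against 12.98 for Saa2 and 14.09 for Saa1. Serpina3m was at least 484-fold higher. All 44 interferon response genes rose (44 adjusted over the list alone, camera adjusted p = 3.9e-23, adjusted p = 0.16 with an estimated correlation), including the GTPase gene Iigp1 (8.0, SE 0.239) and the chemokine gene Cxcl10 (7.91, SE 0.551, or 7.22 without LPS replicate 3). Of 28 antigen presentation genes, 26 rose and 1 fell (27 adjusted over the list alone, camera adjusted p = 1.6e-13, adjusted p = 0.12 with an estimated correlation), with the peptide transporter gene Tap1 at 5.57 (SE 0.175) and the immunoproteasome gene Psmb8 at 4.99 (SE 0.131). Among 27 complement genes, 15 rose and 6 fell (21 adjusted over the list alone, camera adjusted p = 0.035, adjusted p = 0.23 with an estimated correlation), led by C3 (6.69, SE 0.191). That complement call did not hold without LPS replicate 3 (adjusted p = 0.059), with the stricter filter (0.077) or in a fit of the groups compared alone (0.055), and without control replicate 4 the median was 1.52 against 0.91.

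Of 30 tubular injury genes, 28 rose after LPS (29 adjusted over the list alone, camera adjusted p = 8.9e-14, adjusted p = 0.091 with an estimated correlation), and Vim, the vimentin gene, did not pass (0.26, SE 0.133, adjusted p = 0.1), but did in 2 of 25 settings (range of adjusted p 0.0358 to 0.286). Of 35 p53 target genes, 24 rose and 3 fell (27 adjusted over the list alone, camera adjusted p = 0.00043, adjusted p = 0.23 with an estimated correlation). For the integrated stress response, 19 of 32 genes rose and 5 fell (24 adjusted over the list alone, camera adjusted p = 0.002, adjusted p = 0.23 with an estimated correlation). Fgf21, a stress-induced hormone gene, was at least 420-fold higher (adjusted p = 9.05e-08), and Chac1, a glutathione-degrading enzyme gene, rose 35.6-fold (5.14, SE 0.349). Of 36 cell death genes, 28 rose and 5 fell (33 adjusted over the list alone, camera adjusted p = 4.5e-06, adjusted p = 0.097 with an estimated correlation), with Mlkl at 5.58 (SE 0.214). Glucocorticoid response genes rose in 14 of 17 cases and fell in 1 (15 adjusted over the list alone, camera adjusted p = 1.2e-05, adjusted p = 0.23 with an estimated correlation). Pdk4 of that list rose 60.4-fold (5.92, SE 0.179, adjusted p = 9.48e-14). Neutrophil genes rose in 13 of 14 cases (14 adjusted over the list alone, camera adjusted p = 1.8e-06, adjusted p = 0.061 with an estimated correlation), with S100a9 at 7.32 (SE 0.385), or 8.07 without control replicate 4. Ribosomal protein genes rose in 28 of 50 cases (27 adjusted over the list alone, camera adjusted p = 0.003, adjusted p = 0.71 with an estimated correlation), with a median of 0.21. Mmp7, the metalloproteinase matrilysin, rose from 1 control count to 45.1 ± 14.0 CPM (ratio 5159, 95% counting interval 926 to 203800; log2 fold change 11.65, or 13.12 without control replicate 3), in a matrix and fibrosis list that did not pass (15 rose, 11 fell, 26 adjusted over the list alone, adjusted p = 0.57).

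Proximal tubule genes fell after LPS. Of 39 proximal transporter genes, 32 fell and 2 rose (35 adjusted over the list alone, camera adjusted p = 2e-08, adjusted p = 0.36 with an estimated correlation), including Slc2a2, the basolateral glucose transporter gene (-4.55, SE 0.327), and Slc5a12, a lactate transporter gene (-3.39, SE 0.236). Of 38 proximal metabolism genes, 29 fell (29 adjusted over the list alone, camera adjusted p = 7.6e-07, adjusted p = 0.39 with an estimated correlation), among them Gatm, 62.2-fold lower (-5.96, SE 0.151), and G6pc, the last enzyme of glucose release (-3.71, SE 0.437). The largest falls also held Nccrp1, an F-box protein gene (-6.88, SE 0.623), Hsd3b2, a steroid dehydrogenase gene (-5.54, SE 0.242), Btnl9, a butyrophilin-like gene (-5.47, SE 0.379), and Clec2h, a lectin gene (-5.13, SE 0.207). Acmsd, an enzyme gene of tryptophan breakdown (-4.85, SE 0.286), Abca9, a lipid transporter family gene (-4.72, SE 0.215), and Aplnr, the apelin receptor gene (-4.60, SE 0.227), fell too. Oxidative phosphorylation genes fell in 55 of 57 cases (55 adjusted over the list alone, camera adjusted p = 1.8e-12, adjusted p = 0.38 with an estimated correlation), and mitochondrial genome transcripts in 10 of 13 (10 adjusted over the list alone, camera adjusted p = 0.002, adjusted p = 0.38 with an estimated correlation). Cholesterol synthesis genes fell in 17 of 24 cases and rose in 2 (19 adjusted over the list alone, camera adjusted p = 0.00011, adjusted p = 0.23 with an estimated correlation). Fatty acid oxidation genes did not pass as a list (17 rose, 10 fell, 28 adjusted over the list alone, adjusted p = 0.19).

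Thick limb, distal tubule, intercalated cell and podocyte genes fell after LPS. Collecting duct genes did not pass as a list (4 of 12 fell, 4 adjusted over the list alone, adjusted p = 0.14). Of 12 thick ascending limb genes, 11 fell (11 adjusted over the list alone, camera adjusted p = 0.0014, adjusted p = 0.45 with an estimated correlation). Slc12a1, the furosemide-sensitive cotransporter gene, fell from 1019 ± 336 to 72.7 ± 23.9 CPM (-3.81, SE 0.589, adjusted p = 2.49e-05), and Egf fell 8.80-fold (-3.14, SE 0.256, adjusted p = 1.5e-08). Umod did not pass (-0.57, SE 0.482, adjusted p = 0.314), but did without cisplatin replicate 2, whose low Umod enters the shared estimate of spread (adjusted p = 0.0174; range over 25 settings 0.00102 to 0.526). Of 13 distal tubule genes, 8 fell and 2 rose (11 adjusted over the list alone, camera adjusted p = 0.0069, adjusted p = 0.36 with an estimated correlation). Slc12a3 of that list did not pass (-0.31, SE 0.137, adjusted p = 0.0536), and passed without control replicate 5 or cisplatin replicate 1, 2 or 5 (adjusted p = 0.0241 to 0.0438), and in 10 of 25 settings in all (range 0.00456 to 0.142). Intercalated cell genes fell in 11 of 12 cases (11 adjusted over the list alone, camera adjusted p = 1.5e-05, adjusted p = 0.15 with an estimated correlation), led by Slc4a1 (-4.55, SE 0.374). Of 14 podocyte genes, 10 fell and 2 rose (13 adjusted over the list alone, camera adjusted p = 0.0014, adjusted p = 0.36 with an estimated correlation), led by Clic3, a chloride channel family gene (-3.99, SE 0.254). Renin-angiotensin genes fell in 8 of 11 cases and rose in 2 (11 adjusted over the list alone, camera adjusted p = 0.038, adjusted p = 0.28 with an estimated correlation). That call was lost with the stricter filter (adjusted p = 0.085), in a fit of the groups compared alone (0.055) and with cisplatin libraries 3 to 5 alone (0.051). Histone genes fell in 8 of 11 cases and rose in 1 (9 adjusted over the list alone, camera adjusted p = 0.02, adjusted p = 0.39 with an estimated correlation). Erythroid genes did not pass as a list after LPS (2 rose, 2 fell, 4 adjusted over the list alone; median -0.08, adjusted p = 0.73). Macrophage genes did not pass either (11 rose, 7 fell, 18 adjusted over the list alone, adjusted p = 0.17), although Cd14, the endotoxin co-receptor gene, rose 339-fold (8.40, SE 0.178, adjusted p = 3.82e-15).

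**Figure D2:**
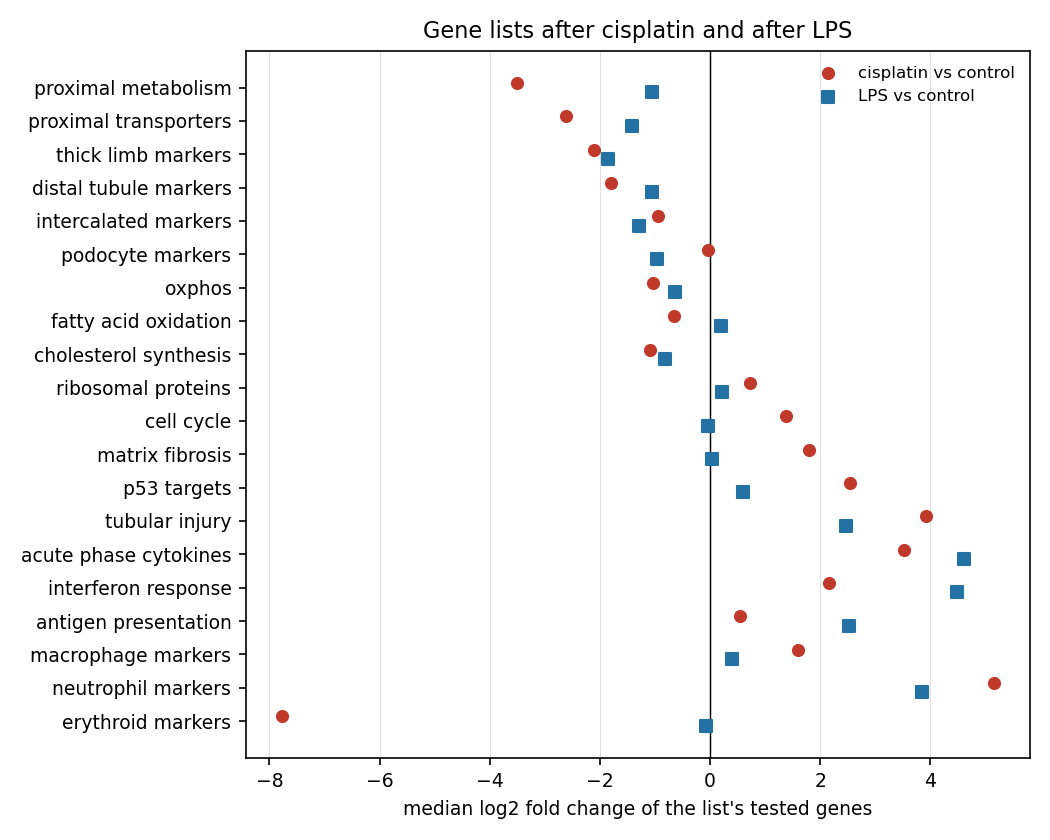
Median log2 fold change of the tested genes in selected gene lists (horizontal axis) after cisplatin and after LPS against control, 5 libraries per group, with lists on the vertical axis. Proximal metabolism genes had medians of -3.51 after cisplatin and -1.05 after LPS, interferon response genes 2.17 and 4.48, and erythroid genes -7.78 and -0.08.

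Much of the response was common to both treatments. Of the genes tested, 7842 changed the same way after cisplatin and after LPS, 4133 higher and 3709 lower, of which 2950 changed at least 2-fold in both. Another 899 changed in opposite directions, 471 of them higher after cisplatin and lower after LPS. Slc34a1, Slc34a3, Kl, Gatm and Egf were among the genes lower in both, and Havcr1, Lcn2, Cdkn1a, C3, Mlkl and S100a9 among those higher in both. Among genes changed the same way, 4590 also differed between the treatments. Of these, 1543 were lower still after cisplatin, as Slc34a1 and Slc34a3 were, and 611 lower still after LPS. Another 1343 were higher still after cisplatin and 1093 higher still after LPS. Across genes, which are not independent replicates, Pearson r between the fold changes was 0.681, the covariance 1.51, and 75.5% had the same sign. Both comparisons used the same controls. In 20 simulations of unchanged groups against those controls 0 genes were shared, with a mean r of 0.0219, a mean covariance of 0.000951 and 50.1% the same sign. The simulated groups were drawn around the means of those same controls, which leaves out the error that both comparisons share. These simulations therefore cannot show what shared controls alone would give. Independent lists of these sizes would share 2272 higher and 1708 lower genes. With the controls divided between the comparisons 20 times, 6461 to 6971 genes were shared and r was 0.633 to 0.663.

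**Figure D3:**
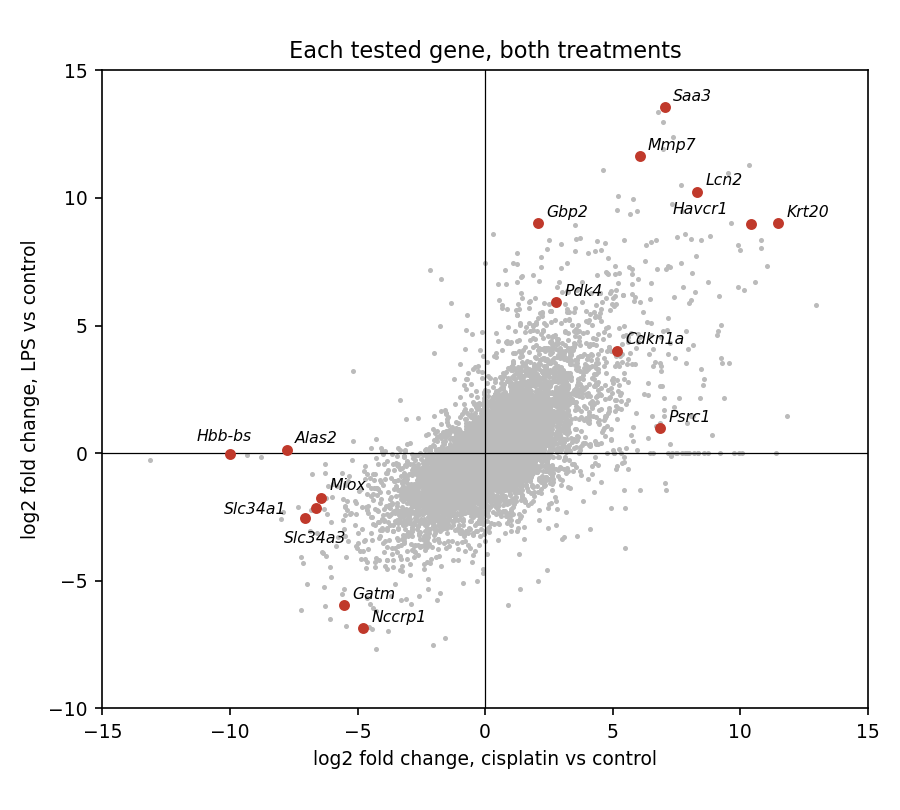
Log2 fold change after LPS (vertical axis) against that after cisplatin (horizontal axis) for the tested genes (grey points, with named genes in red), each against the same 5 controls. Across genes r was 0.681, and Slc34a1 and Slc34a3 lay lower on the cisplatin axis (-6.64 and -7.06) than on the LPS axis (-2.14 and -2.55).

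Compared directly, Eda2r stood at 68.6 ± 9.96 CPM after cisplatin and 1.39 ± 0.175 after LPS (SD, n = 5; log2 difference 5.62, SE 0.196, adjusted p = 1.39e-12), and Psrc1 differed by 5.88 (SE 0.171, adjusted p = 2.84e-13). Gbp2 stood at 43.1 ± 10.1 CPM after cisplatin and 5360 ± 842 after LPS (-6.96, SE 0.188, adjusted p = 1.6e-13). Cdkn1a was higher after cisplatin (1.17, SE 0.162, adjusted p = 1.05e-05) and Lcn2 lower (-1.93, SE 0.278, adjusted p = 1.54e-05). In all, 10460 genes (62.8%) differed, 5291 higher after cisplatin and 5169 lower, of which 3772 differed at least 2-fold (2249 higher, 1523 lower). With total-count scaling 8896 were higher and 2616 lower, or 77.3% higher against 50.6%, and the median of all tested genes was 0.38 against 0.02.

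The genes furthest above LPS were Crct1 (at least 511-fold higher), Lce1d, another gene of the epidermal differentiation cluster (at least 187-fold higher), and Gsta1, a glutathione transferase gene (315-fold; 8.22, SE 0.38). Calcb, a calcitonin gene-related peptide gene with 2 counts in LPS, differed 372-fold (95% counting interval 103 to 3073; log2 difference 8.18, or 10.35 without LPS replicate 1, which held both counts), and Sprr2f differed 147-fold. Of 35 p53 targets, 27 were higher after cisplatin and 2 lower (29 adjusted over the list alone, camera adjusted p = 6.6e-11, adjusted p = 0.13 with an estimated correlation). Cell cycle genes were higher in 46 of 48 cases (47 adjusted over the list alone, camera adjusted p = 8.1e-09, adjusted p = 0.45 with an estimated correlation), including Ccnd1, cyclin D1 (3.14, SE 0.11), and Mki67, the proliferation marker (2.66, SE 0.344). Of 39 matrix and fibrosis genes, 31 were higher and 2 lower (36 adjusted over the list alone, camera adjusted p = 8.9e-10, adjusted p = 0.45 with an estimated correlation). Col1a1, a collagen I chain gene, was higher after cisplatin (3.60, SE 0.287), and Mmp7 lower (-5.59, SE 0.227). Tubular injury genes were higher in 21 of 30 cases and lower in 5 (27 adjusted over the list alone, camera adjusted p = 0.0016, adjusted p = 0.45 with an estimated correlation), with Fgb among the lower (-4.87, SE 0.215). Ribosomal protein genes were higher in 45 of 50 cases (45 adjusted over the list alone, camera adjusted p = 1.2e-10, adjusted p = 0.45 with an estimated correlation).

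Cell type lists also separated the treatments. Stromal genes were higher after cisplatin in 12 of 15 cases (12 adjusted over the list alone, camera adjusted p = 0.00038, adjusted p = 0.4 with an estimated correlation). Podocyte genes were higher in 11 of 14 and lower in 2 (13 adjusted over the list alone, camera adjusted p = 0.0018, adjusted p = 0.45 with an estimated correlation), led by Clic3 (3.52, SE 0.253). Of 22 macrophage genes, 15 were higher and 5 lower (20 adjusted over the list alone, camera adjusted p = 0.022, adjusted p = 0.48 with an estimated correlation), but the list did not pass under total-count scaling (adjusted p = 0.32) or with the stricter filter (0.075). Mrc1, the mannose receptor gene of tissue macrophages, was higher (3.95, SE 0.232), and Cd14 lower (-4.83, SE 0.148). Histone genes were higher in 8 of 11 and lower in 2 (10 adjusted over the list alone, camera adjusted p = 0.039, adjusted p = 0.48 with an estimated correlation), with a median of 1.13, or 1.73 without LPS replicate 3, and total-count scaling ended the call (adjusted p = 0.16). Intercalated cell genes were higher in 7 of 12 and lower in 1 (8 adjusted over the list alone, camera adjusted p = 0.041, adjusted p = 0.48 with an estimated correlation). That call was lost without cisplatin replicate 5 (adjusted p = 0.073), LPS replicate 3 (0.06) or LPS replicate 5 (0.055), with the replicate block (0.055), in a fit of those groups alone (0.053) and under total-count scaling (0.083).

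Of 44 interferon response genes, 43 were lower after cisplatin than after LPS and 1 higher (44 adjusted over the list alone, camera adjusted p = 5.1e-17, adjusted p = 0.4 with an estimated correlation), with the GTPase genes Gbp10 (-9.31, SE 0.319) and Gbp6 (-6.37, SE 0.233) among the lower. Antigen presentation genes were lower in 27 of 28 cases (27 adjusted over the list alone, camera adjusted p = 3.7e-17, adjusted p = 0.14 with an estimated correlation), led by Ciita, the MHC class II transactivator gene (-4.49, SE 0.249). Of 48 acute-phase and cytokine genes, 30 were lower and 9 higher (39 adjusted over the list alone, camera adjusted p = 0.00025, adjusted p = 0.45 with an estimated correlation). Nos2 was lower (-7.22, SE 0.923, adjusted p = 4.26e-06), and -6.18 without LPS replicate 3, which held 342 CPM of an LPS mean of 112 ± 142. Integrated stress response genes were lower in 22 of 32 cases and higher in 3 (25 adjusted over the list alone, camera adjusted p = 0.00037, adjusted p = 0.4 with an estimated correlation), with Fgf21 at -6.49 (SE 0.518). Fatty acid oxidation genes were lower in 32 of 36 cases and higher in 1 (33 adjusted over the list alone, camera adjusted p = 5.2e-10, adjusted p = 0.45 with an estimated correlation), with Pdk4 at -3.13 (SE 0.156). Glucocorticoid response genes, which include Pdk4, Lcn2 and Cdkn1a, were lower in 9 of 17 cases and higher in 2 (11 adjusted over the list alone, camera adjusted p = 0.034, adjusted p = 0.56 with an estimated correlation). Their call was lost without cisplatin replicate 2 (adjusted p = 0.066), without LPS replicate 3 (0.063), with the stricter filter (0.077) and with cisplatin libraries 3 to 5 alone (0.079).

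Proximal tubule genes were also lower after cisplatin. Proximal metabolism genes were lower in 36 of 38 cases and higher in 1 (38 adjusted over the list alone, camera adjusted p = 8.1e-14, adjusted p = 0.4 with an estimated correlation), with Miox at -4.65 (SE 0.119). Of 39 proximal transporter genes, 29 were lower and 6 higher (35 adjusted over the list alone, camera adjusted p = 2.2e-06, adjusted p = 0.48 with an estimated correlation). Phosphate-handling genes were lower in 9 of 18 cases and higher in 3 (12 adjusted over the list alone, camera adjusted p = 0.027, adjusted p = 0.48 with an estimated correlation), and Pth1r, the parathyroid hormone receptor gene, was lower (-1.68, SE 0.114, adjusted p = 2.83e-09). The median of that list was -0.30, or -0.20 without cisplatin replicate 1, its sign turned under total-count scaling, and its call was lost with the stricter filter (adjusted p = 0.075) and with cisplatin libraries 3 to 5 alone (0.05). Oxidative phosphorylation genes were lower in 33 of 57 cases and higher in 2 (35 adjusted over the list alone, camera adjusted p = 1.1e-05, adjusted p = 0.63 with an estimated correlation), with a median of -0.32 whose sign turned under total-count scaling. Cholesterol synthesis genes were lower in 12 of 24 and higher in 3 (15 adjusted over the list alone, camera adjusted p = 0.046, adjusted p = 0.54 with an estimated correlation). The median of this list was -0.23 and turned to 0.12 under total-count scaling (adjusted p = 0.16). Its call was lost without control replicate 3 (adjusted p = 0.052), cisplatin replicate 1 (0.085) or 2 (0.07), or LPS replicate 1 (0.05), 2 (0.052) or 5 (0.055). It was also lost with the stricter filter (0.16), the replicate block (0.06), a fit of those groups alone (0.053) and cisplatin libraries 3 to 5 alone (0.14).

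Red cell and distal nephron transcripts differed as well. Of 9 erythroid genes, 7 were lower after cisplatin and 1 higher (9 adjusted over the list alone), with a median of -7.92 (camera adjusted p = 0.001, adjusted p = 0.4 with an estimated correlation). Hbb-bt was at least 1790-fold lower, and Hbb-bs (-9.95, SE 0.396), Hba-a2 (-9.26, SE 0.405), Hba-a1 (-8.64, SE 0.468, or -9.46 without cisplatin replicate 1) and Alas2 (-7.92, SE 0.508) were lower too. Distal tubule genes were lower in 11 of 13 cases and higher in 2 (13 adjusted over the list alone, camera adjusted p = 0.0051, adjusted p = 0.45 with an estimated correlation). Thick ascending limb genes did not pass as a list (2 higher, 2 lower, 2 adjusted over the list alone, adjusted p = 0.49). Egf was lower after cisplatin (-3.44, SE 0.261, adjusted p = 1.07e-08), as was Umod (-1.88, SE 0.497, adjusted p = 0.00349). Slc12a1 was higher (1.46, SE 0.539, adjusted p = 0.0269), a call lost in 8 of 25 settings, including without cisplatin replicate 4 (adjusted p = 0.0606) or 5 (0.091) and without LPS replicate 1 (0.0515), 4 (0.0542) or 5 (0.0611). Its groups overlapped, because cisplatin replicate 2, at 11.15 CPM, lay below every LPS library (45.58 to 110.5 CPM). The other cisplatin libraries held 137 to 382.4 CPM.

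**Figure D4:**
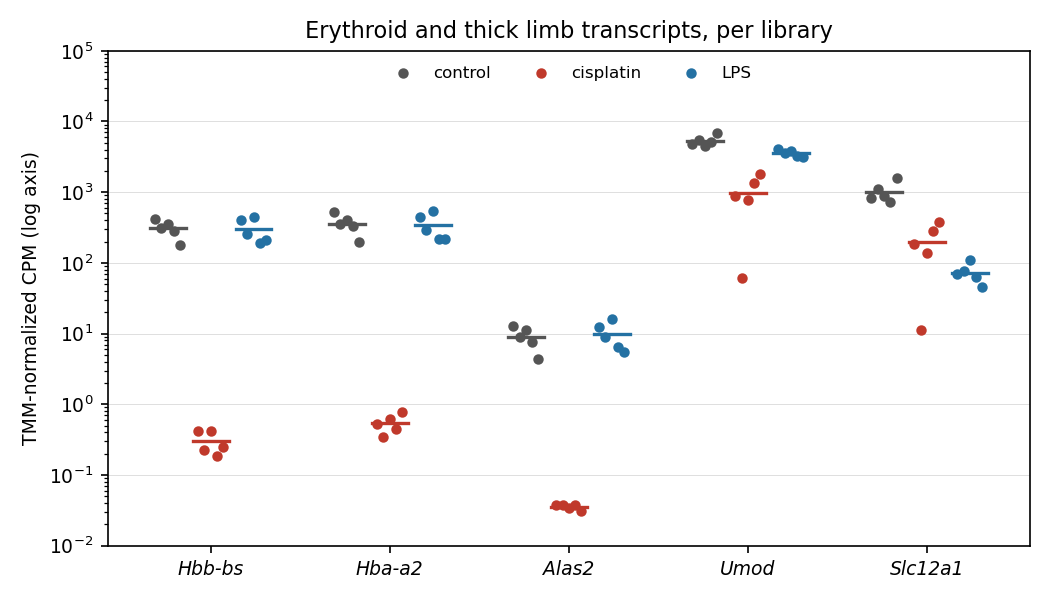
Level per library in CPM on a log axis for erythroid and thick ascending limb genes in the control, cisplatin and LPS groups (5 libraries each, points), with a line at the group mean. Hbb-bs averaged 308 CPM in control, 0.299 after cisplatin and 300.5 after LPS, and cisplatin replicate 2 held 61.5 CPM of Umod against 771 to 1810 in the other cisplatin libraries.

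With the preset correlation, camera called 24 lists after cisplatin (12 higher, 12 lower), 22 after LPS (11 and 11) and 23 between treatments (10 and 13), of 39 tested. With the correlation estimated per list it called 0, 0 and 0, with 9, 7 and 4 lists at an unadjusted p under 0.05 and lowest adjusted p of 0.11, 0.061 and 0.13. The list calls therefore rest on the preset correlation, while the calls of single genes do not.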

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

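The tests of Alas2 alone and of proximal transporters in cisplatin replicate 2, with and without replicate 1, were chosen only after the results were seen. The other tests of explanations and the regroupings, with the bounds they were held to, were written before. For the tests of single libraries, a rule was set after a first result was seen, as given there.

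Globin and Alas2 transcripts were nearly absent after cisplatin (median -7.78 for the erythroid list, with 1 of 9 genes rising), and the list did not pass after LPS. Removal of globin transcripts from the cisplatin libraries would have spared other red cell genes. Alas2, which is not a globin gene, fell by 7.78, so removal of globins alone would not account for that gene. As Alas2 belongs to the list that shows the fall and was picked after its value was seen, it does not test removal for the globins. Epb42 at -0.233 (edgeR adjusted p = 0.637) leaves removal open for the list as a whole. Less blood in the cisplatin kidneys would have lowered platelet genes too, but their median was 1.14 higher, past the bound set against less blood. Only 4 of 12 platelet genes were tested, at 0.293 to 4.65 CPM in control and with log2 fold changes of -0.0929 to 1.56. Of these, 2 passed the threshold as higher, so the platelet genes do not follow blood content alone. Their median therefore argues against less blood only weakly. A lack of young red cells after cisplatin and not after LPS stays open, because Alas2 in cisplatin against LPS, at -7.92, belongs to the list that shows the fall and cannot test it.

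Thick ascending limb transcripts were lowest in cisplatin replicate 2, with a median of -2.15 against the other 4 cisplatin libraries and 11 of 12 genes below -1. A piece of kidney with less medulla may have lowered collecting duct genes as well, and their median there was -0.942. All 12 were lower there (highest -0.264), while all 14 podocyte genes, for which no bound was set, were higher (median 0.254, lowest 0.0224). The collecting duct median did not reach the bound for either reading, so less medulla cannot be told apart from a loss in the thick limb. Heavier injury of all tubule segments predicted distal tubule genes to fall alike, and their median of -0.581 lay between the bounds and left this open. Proximal transporters stood at -0.0851 (SD of members 0.616; 24 lower and 15 higher), or -0.361 (SD 0.622; 31 lower and 8 higher) without replicate 1, itself low for them at -0.712. This argues, narrowly, against a proximal fall of 1 or more, and a smaller one stays open.

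Regrouping the libraries tested whether chance could give results as large. Of 100 splits drawn for each comparison, 1, the real split, reached its number of changed genes. The real numbers were 11947 after cisplatin (highest other 14), 11057 after LPS (highest other 0) and 10460 between treatments (highest other 875). A split that mixes the groups puts their difference into the spread within groups, so it tends to call few genes in any case. That the real split was highest therefore does not exclude chance, and 1 of 100 is the smallest share possible. For genes changed the same way, 1 of 100 regroupings, the real grouping, reached 7842 (highest other 5599), and the same limit holds there. For lists passing camera with the preset correlation, 27, 9 and 6 of the 100 splits reached the real numbers of 24, 22 and 23 (highest others 30, 26 and 24). Each mixed split was uneven and kept part of the difference between the groups, which lists can still pick up. These splits therefore do not show how many lists chance alone would give, and chance is not excluded for the number of lists.

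Single libraries stood far from the other 4 of their group in 16 of 367 tests (4.36%), about the 1 in 20 that chance gives. The value given is the gap to the nearest other library as a share of the group's range, and groups with at most 3 counts were left out by a rule set after a first result was seen. In control, replicate 2 stood apart with high Saa1 (0.807) and low Epb42 (0.769), and replicate 3 with low Hsd11b2 (0.768). Control replicate 4 was high for Slc2a2 (0.775) and the distal tubule list (0.713), and control replicate 5 was high for Hlf (0.874) and low for the podocyte list (0.715). After cisplatin, replicate 1 was high for Cidec (0.819) and the complement list (0.719), and replicate 2 was high for the cell death list (0.749) and low for Umod (0.747) and Hsd11b2 (0.741). After LPS, replicate 3 was high for the stromal list (0.913) and Hsd3b2 (0.734) and low for Ciita (0.746). LPS replicate 4 was low for Col1a1 (0.858).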

How the results depend on the processing

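Of the results below, those with total-count scaling, the whole reads recovered from the depth-scaled table and cisplatin libraries 3 to 5 alone come from tests chosen after the data were seen.

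Slc34a1 and Slc34a3 stayed lower, past the threshold, after both treatments in every setting run. Leaving out each library in turn, Slc34a1 ranged from -6.765 to -6.538 after cisplatin and from -2.216 to -2.066 after LPS, and Slc34a3 from -7.461 to -6.809 and from -2.615 to -2.466. The number of genes changed in cisplatin vs control ranged from 11655 to 12393, of genes changed in LPS vs control from 10698 to 11251, of genes changed in cisplatin vs LPS from 10007 to 10534, and of genes changed the same way by both treatments from 7506 to 7876. Lists called with the preset correlation numbered 24 throughout after cisplatin, 21 to 22 after LPS and 21 to 23 between treatments. DESeq2 called 12922, 11378, 11126 and 7961 genes in the same order, the recovered whole reads 11792, 10891, 10313 and 7741, and cisplatin libraries 3 to 5 alone 11211, 11369, 9309 and 7749. A minimum of 2-fold left 5604, 4545, 3772 and 2950 genes, by its own construction. With an estimated correlation camera called 0, 0 and 0 lists, with lowest adjusted p of 0.11, 0.061 and 0.13, and the cause was not tested.

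The replicate numbers showed no clear pairing of the samples, though a weak pairing cannot be excluded. Same-numbered libraries of different groups had r of -0.199 to 0.128 between their deviations from group means, over 0.1 in 1 of 15 pairs, and 2 of 15 libraries correlated best with their own number. With the replicate block, genes changed in cisplatin vs control numbered 11743, genes changed in LPS vs control 10735, genes changed in cisplatin vs LPS 10098, and genes changed the same way by both treatments 7593, with 24, 22 and 21 lists. Between treatments the cholesterol synthesis and intercalated cell lists and Slc12a1 lost their calls with the block, and it changed no other call of a named gene or list.

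Directions turned for 3 genes that had not passed. Adipoq after cisplatin ranged from -0.5188 (without cisplatin replicate 1) to 4.274 when single libraries were left out, and was -0.1263 with cisplatin libraries 3 to 5 alone, so its rise rests on replicate 1. Fgfr1 was 0.2804 and Epb42 0.1371 after cisplatin under total-count scaling, and Epb42 was 0.03617 with cisplatin libraries 3 to 5 alone, and the cause was not tested. Of the named genes, Slc12a1 between treatments lost its call, in 8 of 25 settings, with values of 0.815 to 1.88 and adjusted p of 0.000112 to 0.3 over the settings. Calls were gained in at least 1 setting by Adipoq, Fgfr1 and Nos2 after cisplatin and by Slc12a3, Umod and Vim after LPS. List calls with the preset correlation were lost in some setting for complement and renin-angiotensin genes after LPS, and for cholesterol synthesis, glucocorticoid response, histone, intercalated cell, macrophage and phosphate-handling genes between treatments, but for none after cisplatin. Under total-count scaling the medians of the phosphate-handling, oxidative phosphorylation, cholesterol synthesis, thick limb, cell death, heat shock, renin-angiotensin, T and NK cell and mitochondrial genome lists changed sign between treatments, so their direction there depends on the scaling. Quantile normalization and a smaller pseudocount were planned for FPKM values only and did not apply, and DESeq2 gave no adjusted p for Cidec after cisplatin. Depth limits genes such as Alas2, which had 5 counts over the 5 cisplatin libraries.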

Other observations

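The tests given here of gene span in the LPS libraries, and the choice of Rn7sk and of unnamed transcripts, were made only after the results were seen.

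Of 19 circadian clock genes, 7 rose and 8 fell after LPS (15 adjusted over the list alone), against 66.3% of all genes changed, and the list did not pass (camera adjusted p = 0.57), with a median of 0.04 and a mean of -0.51. Hlf, a clock-controlled transcription factor gene, fell from 98.7 ± 10.7 to 4.89 ± 0.336 CPM (SD, n = 5; log2 fold change -4.33, SE 0.214, edgeR adjusted p = 3.37e-11), and Per3, a period gene, fell 8.89-fold (-3.16, SE 0.206, adjusted p = 9.62e-10), while Nfil3 (2.25, SE 0.166) and Cry1 (2.05, SE 0.172) rose. Among 13 T and NK cell genes, 7 rose and 2 fell after LPS (9 adjusted over the list alone, camera adjusted p = 0.21). Gzmb, the granzyme B gene of cytotoxic lymphocytes, rose from 0.150 ± 0.119 to 3.15 ± 0.954 CPM (4.34, SE 0.377, adjusted p = 3.23e-08). Rn7sk, the small RNA that holds the elongation factor P-TEFb inactive, rose from 1.02 ± 0.314 to 8.87 ± 1.71 CPM after cisplatin (3.12, SE 0.211, adjusted p = 1.12e-09) and stood at 0.898 ± 0.162 CPM after LPS (-0.17, adjusted p = 0.528). Transcripts without a symbol took 0.124% of counts in control, 0.648% after cisplatin and 0.570% after LPS. Among them, ENSMUSG00000121069 stood at 214 ± 17.2 CPM in control, 2646 ± 254 after cisplatin and 2895 ± 638 after LPS, and ENSMUSG00000121137 at 98.3 ± 12.2, 1284 ± 189 and 1358 ± 319 CPM. Ddx3y, on the Y chromosome, stood at 14.6 to 41.8 CPM in the 15 libraries, and Xist, expressed from the inactive X chromosome, at 0 to 0.149 CPM.

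The remaining lists did not pass camera with the preset correlation. After cisplatin, antigen presentation genes (15 rose, 8 fell, 24 adjusted over the list alone, adjusted p = 0.11), stromal genes (8 and 1, 9 alone, 0.15), NRF2 targets (17 and 10, 27 alone, 0.23) and integrated stress response genes (18 and 12, 30 alone, 0.77) were among them. So were clock genes (8 and 7, 15 alone, 0.8), podocyte genes (3 and 4, 6 alone, 0.67), T and NK cell genes (4 and 1, 4 alone, 0.92) and B cell genes (1 and 2, 1 alone, 0.77). Heat shock genes (5 and 7, 13 alone, 0.4) and histone genes (3 and 4, 7 alone, 0.77) had medians of -0.27 and -0.31 and means of 0.01 and 0.23, with the test pointing down. Endothelial genes (5 and 3, 7 alone, 0.97) and urothelial genes (1 and 0, 1 alone, 0.88) had medians of 0.08 and 0.51 with the test pointing down, but under total-count scaling 10 endothelial genes rose and 0 fell, with a median of 0.469. Cisplatin transport genes (6 and 7, 13 alone, 0.77) had a median of 0.10, a mean of -0.05 and a test pointing down. Under total-count scaling the medians of the heat shock, clock, podocyte, B cell and histone lists changed sign.

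After LPS, the lists that did not pass held heat shock genes (3 rose, 8 fell, 11 adjusted over the list alone, adjusted p = 0.12) and stromal genes (2 and 7, 9 alone, 0.15). They also held endothelial genes (7 and 9, 16 alone, 0.21), NRF2 targets (16 and 14, 30 alone, 0.57), cell cycle genes (9 and 8, 14 alone, 0.73) and B cell genes (1 and 1, 2 alone, 0.57). Adipocyte genes (4 and 1, 5 alone, 0.57) and urothelial genes (0 and 0, 0 alone, 0.73) did not pass either. Cisplatin transport genes (4 and 8, 12 alone, 0.57) had a median of -0.39 and a mean of 0.32, with the test pointing down. Between treatments, complement genes (13 higher after cisplatin, 12 lower, 25 adjusted over the list alone, adjusted p = 0.52), NRF2 targets (15 and 12, 27 alone, 0.49), cell death genes (10 and 16, 26 alone, 0.4) and clock genes (10 and 6, 16 alone, 0.3) did not pass. The same held for renin-angiotensin genes (2 and 3, 5 alone, 0.69), collecting duct genes (4 and 3, 7 alone, 0.79), endothelial genes (11 and 4, 15 alone, 0.12) and T and NK cell genes (1 and 6, 7 alone, 0.2). It also held for B cell genes (1 and 1, 1 alone, 0.79), adipocyte genes (3 and 0, 1 alone, 0.83), urothelial genes (1 and 0, 1 alone, 0.83), mitochondrial genome transcripts (0 and 6, 5 alone, 0.15) and cisplatin transport genes (6 and 8, 14 alone, 0.52). Neutrophil genes (7 and 3, 10 alone, 0.49) had a median of 0.40 and a mean of -0.0039, and heat shock genes (5 and 5, 10 alone, 0.98) a median of -0.00822 and a mean of 0.17. Lists of adrenal and sex-linked genes, with 3 and 4 tested members, were not tested.

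Cisplatin forms DNA adducts that stall transcription, which might lower long genes most. Across 16351 genes, which are not independent replicates, the cisplatin fold change and gene span had a Spearman rho of -0.0703, or -0.106 given GC content and -0.0798 given mRNA length, which argues against either as the whole source of this weak trend. After LPS the rho was -0.0635, and in cisplatin against LPS it was -0.00639, or -0.0462 given GC content, -0.0418 given mRNA length and -0.0629 given both. The unadjusted value lay between the bounds set for it, so how far the trend is stronger after cisplatin stays open and depends on the adjustment. Given GC content and mRNA length, each LPS library had a negative value too, the highest being -0.0323, against -0.0117 to 0.00575 in control and -0.106 to -0.0922 after cisplatin, so a trend absent after LPS is argued against.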
